A study of Homo sapiens with 4 samples.

How the data were processed

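Total RNA of the human liver cancer lines Li-7 and HEP-G2 was labelled with biotin and hybridised to Affymetrix expression arrays, 1 array per line and treatment. The treatments were a miR-4730 mimic, given at 3 nM by lipid transfection 24 h after seeding per the labels' protocols, and a negative control oligonucleotide of the same supplier. The 4 groups were taken from the sample titles. Culture media differed between the lines per the labels' protocols, so line and medium are not separable.

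The authors deposited 1 table of summarised probe-set values on a log2-like scale. The submitters' processing notes name Affymetrix Expression Console and Transcriptome Analysis Console, without versions. Background correction, normalization, summarisation and the log base are not given in the sources used here. The values run from 1.48 to 18.3 with like quartiles on all arrays, and were read as log2. The brightest values lie above what a plain log2 of usual scanner readings reaches, so the scale may be stretched or shifted, and folds are on the deposited scale. Negative control probe sets had medians of 4.12 on both Li-7 arrays, 4.34 on the HEP-G2 control and 4.26 on the HEP-G2 mimic array. Their 95th percentiles were 8.72, 7.99, 8.35 and 8.20 in the order Li-7 control, Li-7 mimic, HEP-G2 control and HEP-G2 mimic.

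Of 24351 probe sets, 17709 carried exactly 1 gene name in the platform annotation, 0 carried several, 3739 carried none used here, 612 were negative controls, 2197 positive controls and 94 spike-in or background controls. All 17709 Entrez identifiers matched the RefSeq gene table (GRCh38.p14), whose current symbols were used. The deposited table names no genome build, so no coordinates are given. Where a gene had several probe sets (20 of 17687 genes), the one with the highest mean over the arrays stood for it. Genes with a mean at or above the 30th percentile of all named genes (4.90) were kept, which left 12381.

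Deposited values were analysed without further normalization in R 4.3.3 with limma 3.58.1. The mimic response was fitted as the treatment coefficient of a linear model with cell line and treatment (lmFit and eBayes), and the cell line difference as the line coefficient of the same fit. Adjustment was by Benjamini-Hochberg with a threshold of 0.05. The model leaves 1 residual degree of freedom per gene, moderated over genes with 5.85 prior degrees of freedom. Its p values therefore measure the disagreement between the lines, not a spread between replicate cultures, which was not measured. Responses within a line are differences of single arrays with no test, counted at 2-fold. In text on single genes, changes are mimic minus control.

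Before the data were examined, 27 gene lists with 610 entries, the tests, the rule for named genes and the alternatives were fixed. Of the entries, 527 had a probe set here and 492 were among the genes tested, and the others were not analysed here. Lists were tested with camera at a preset inter-gene correlation of 0.01 and again with the estimated correlation, and were adjusted over the 27 lists. For each line alone, a list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Named genes were HMGA1 and HMGA2, the 10 largest rises and falls past the threshold with the same sign in both lines, the 10 largest of each direction in each line, the 5 largest differences between the lines in each direction, the 10 largest line differences in each direction, and up to 4 members per list with the largest absolute mean change. Any other gene was named after its values were seen.

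The procedure was tested on simulated arrays for the common mimic response (20 runs over 12381 genes, 200 of them changed). It recovered 9.48% of genes changed by 1 log2 unit, 89.3% of those changed by 2 and 98.9% of those changed by 3. Of its calls, 9.84% were false, above the nominal share, and the estimated prior degrees of freedom ran from 4.69 to 12.04 against 5.85 simulated. The cause of the excess was not tested. In the same simulation for the lists of the common mimic response, all 20 lists of 30 genes shifted by 0.5 were called at the preset correlation. Of 20 unshifted lists 0 were, and 0 of the 20 shifted lists were called with the estimated correlation. At that shift, a call missing in that run is therefore no evidence against a list, and larger shifts were not simulated. The simulated genes varied independently, so false calls at the preset correlation for lists whose genes move together were not measured.

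Alternatives were quantile normalization, median centring, cyclic loess, no filter, a filter at the median gene, the mean of a gene's probe sets, eBayes with an intensity trend or robust, an ordinary t statistic, a model without the other factor, a 1.5-fold limit for single lines, and the estimated correlation for lists. A filter on the 95th percentile of the negative control probe sets was added after seeing the data. A search for seed sites in 3 prime UTRs was planned and not run, as no transcript sequences were used here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.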

Results

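Gene expression was measured in human liver cancer cells that had received either a synthetic mimic of the microRNA miR-4730 or a negative control oligonucleotide. The cells were Li-7 and HEP-G2, a pair of established liver cancer lines, which gave 4 groups with 1 Affymetrix array in each and no replicate array in any group. Each array held 24351 probe sets. Median values were 7.17 on both Li-7 arrays, 7.05 on the HEP-G2 control array and 7.03 on the HEP-G2 mimic array, on the deposited log2-like scale. Of 17687 named genes, between 6494 (Li-7 control) and 7557 (Li-7 mimic) lay above the 95th percentile of the negative control probe sets of their array. Over 12381 genes tested, the correlation across genes between control and mimic was 0.978 in Li-7 and 0.972 in HEP-G2, against 0.780 between the control arrays of the lines. Folds below are on the deposited scale, whose log base and normalization are not stated, and the number of arrays limits their precision.

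The series names HMGA1, an architectural chromatin protein of the high mobility group, as the target of miR-4730 under study. HMGA1 fell with the mimic in both lines. Its value went from 14.93 to 10.91 in Li-7, a difference of -4.02 and the lowest of all 12381 genes there. In HEP-G2 it went from 14.79 to 11.61, a difference of -3.17 and rank 4 from the lowest. The mean change of -3.59 (SE 0.29, 2 lines) corresponds to 12.1-fold and passed the limma test with Benjamini-Hochberg adjustment (adjusted p = 0.0241). The related gene HMGA2 stood at 7.74 and 9.89 in Li-7 and at 8.45 and 8.35 in HEP-G2, control and mimic respectively, and did not pass (mean change 1.03, SE 0.49, adjusted p = 0.310), its Li-7 control value lying under the 95th percentile of the negative control probe sets. The HMGA1 call was lost with an ordinary t statistic (adjusted p = 0.640) and with cell line left out of the model (adjusted p = 1), at the same size of change. Those settings passed 1 and 0 of all genes, so the loss is not particular to HMGA1.

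**Figure D1:**
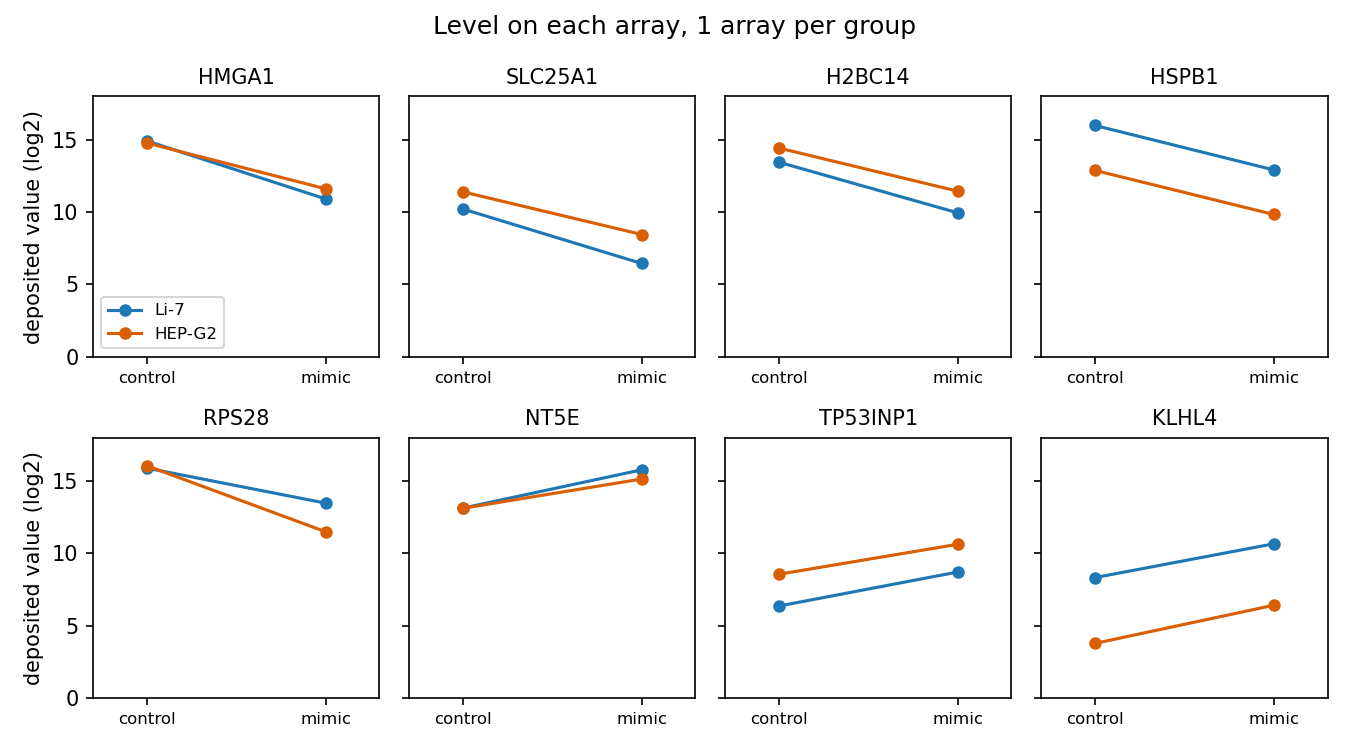
Deposited value (log2, y axis) on the control and mimic array (x axis) of Li-7 and HEP-G2 for 8 named genes, each point 1 array and each line joining the arrays of one cell line. HMGA1 goes from 14.93 to 10.91 in Li-7 and from 14.79 to 11.61 in HEP-G2, while NT5E goes from 13.13 to 15.78 and from 13.12 to 15.15.

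Of the genes that passed the common test, 42 fell and 10 rose. The split was more even after quantile normalization, where 58.7% of 465 calls fell. As deposited, 62.6% of the 465 genes with the lowest p fell, so much of that shift went with the larger number of calls. Among the genes that passed the test, the largest mean falls beside HMGA1 were those of RPS28, a protein of the small ribosomal subunit (-3.50), SLC25A1, the mitochondrial citrate carrier (-3.36), H2BC14, a histone H2B gene (-3.24), and HSPB1, a small heat shock protein (-3.06). They were followed by GNPDA1, an enzyme of amino sugar metabolism (-2.86), CLN6, a protein of the endoplasmic reticulum (-2.85), TBL1X, a subunit of a nuclear corepressor complex (-2.74), ATP5F1D, a subunit of ATP synthase (-2.72), and ASNS, asparagine synthetase (-2.68). The largest mean rises among the genes that passed were those of KLHL4, a kelch-like protein (2.49), NT5E, the cell surface enzyme CD73 that makes adenosine (2.34), SEMA7A, a membrane-anchored semaphorin (2.28), TP53INP1, a p53-inducible gene (2.22), and DTNA, a dystrobrevin (2.18). SUCO (2.08), SLC16A4, of the monocarboxylate transporter family (2.33 in Li-7 and 1.67 in HEP-G2), MAP3K12, a kinase (1.97), SAMTOR, a sensor of S-adenosylmethionine (1.82), and PALMD (1.82) completed the genes that rose. Larger mean changes that did not pass included those of TMC7 (3.17, adjusted p = 0.0601) and TTYH3 (-2.76, adjusted p = 0.0738). SEs of the genes that passed and are named here ran from 0.24 to 0.48, and the widest was that of RPS28, which stood at -2.42 in Li-7 and -4.57 in HEP-G2.

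In all, 52 of 12381 genes passed the limma test at an adjusted p of 0.05, 42 lower and 10 higher with the mimic (80.8% lower), each with the same sign in both lines. Their adjusted p values lay between 0.0241 and 0.0499, and the smallest mean change among them was 1.74 in size. Chosen after their values were seen, the other genes that fell included the transcription factors TEAD4 (-2.44) and E2F8 (-2.30), the recombination and repair genes BRIP1 (-1.74) and MND1 (-1.86), the kinase ARAF (-2.14), and AKT1S1, an inhibitor subunit of mTORC1 (-1.83). POM121 (-2.51) and POM121C (-2.22) also fell, but they are near-identical copies whose probes may be shared, and RPS28 and H2BC14 have close copies too. Many calls involve values under the 95th percentile of the negative control probe sets, where the size of a change is uncertain. Of the 10 genes that rose, 9 lay under it on the Li-7 control array (NT5E being the exception), 4 on the HEP-G2 control array (KLHL4, DTNA, MAP3K12 and SAMTOR), and DTNA on every array. Of the 42 that fell, 21 lay above it on all arrays, among them HMGA1, RPS28, H2BC14, HSPB1 and ATP5F1D, while MCM10 and NPRL3 lay under it on all. With the mimic, 12 of the 42 lay under it in both lines, GNPDA1 and TBL1X among them, and SLC25A1 and ASNS did so in Li-7 and CLN6 in HEP-G2. TEAD4 lay under it on both Li-7 arrays and on the HEP-G2 mimic array. With 1 array per group the spread came from the disagreement between the lines, with 1 residual degree of freedom per gene. The count was 23 after cyclic loess, 465 after quantile normalization (58.7% lower), 1 with an ordinary t statistic and 0 with cell line left out of the model.

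**Figure D2:**
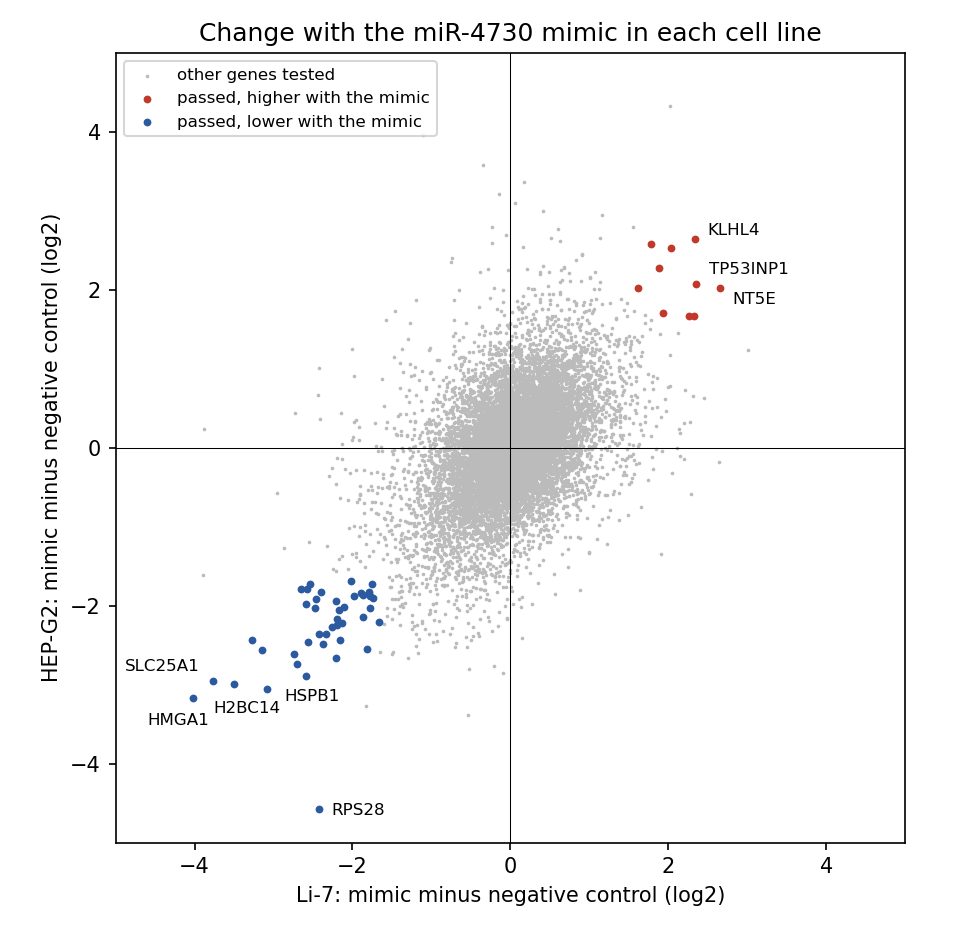
Difference between the mimic and the negative control array (log2) in Li-7 (x axis) and in HEP-G2 (y axis) for the 12381 genes tested, each point 1 gene. The 42 genes that fell and the 10 that rose in the common test are coloured, with HMGA1 at -4.02 and -3.17.

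Genes of DNA replication and the G1/S transition were lower with the mimic in both lines. Of 32 measured members, 31 had a negative mean change and the list median was -1.33. RFC3, a clamp loader subunit (-2.26), and MCM10, a replication initiation factor (-2.18), fell in the test over all genes, and 29 members fell when adjusted over the list alone. MCM10 lay under the 95th percentile of the negative control probe sets on all 4 arrays and RFC3 on none. TK1, thymidine kinase, stood at -1.88 (adjusted p = 0.0803) and FEN1, the flap endonuclease, at -1.85 (adjusted p = 0.0520). Among 16 DNA repair genes the median was -0.77. RAD54L (-1.83, under that percentile on both mimic arrays) and BRCA1 (-1.81, under it on the HEP-G2 mimic array) fell over all genes, and 9 members fell when adjusted over the list alone. With camera at a preset correlation, both lists were called down (adjusted p = 1.6e-20 and 1.42e-06). With an estimated correlation neither was (adjusted p = 0.740 for each). That run called no list in these data and missed every shifted list of the simulation, so it cannot decide here or below.

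The 31 mitosis genes all had a negative mean change, with a median of -1.11, but most of it came from HEP-G2. The median was -0.27 in Li-7 and -1.91 in HEP-G2, and 27 members were at least 2-fold lower in HEP-G2 against 0 in Li-7. NUSAP1, a spindle protein, stood at -0.70 in Li-7 and -2.53 in HEP-G2, BIRC5, survivin, at -0.55 and -2.52, and CDK1, the mitotic kinase, at -0.96 and -2.07. None of the 31 passed over all genes and 9 fell when adjusted over the list alone. The list was called down by camera (adjusted p = 1.52e-11), but not with an estimated correlation (adjusted p = 0.740), which called no list. The difference between the lines was not tested, since each line had 1 array per group.

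Heat shock genes and the high mobility group genes were the other lists called down (camera's adjusted p = 0.000568 and 0.00994). Neither was called with an estimated correlation (adjusted p = 0.740 for each), which called no list. HSPB1 was the 1 of 10 heat shock genes that fell over all genes, 3 fell when adjusted over the list alone, and the median was -0.44. HSPA1A, an inducible HSP70, stood at -1.91 (adjusted p = 0.0520). A broader set of 57 genes, gathered by heat shock symbols after the results were seen, had medians of -0.135 in Li-7 and 0.022 in HEP-G2. The fall of the fixed list thus did not extend to that set in HEP-G2. The high mobility group list, also of 10 genes, had a median of -0.48, with HMGA1 alone passing over all genes and 2 falling when adjusted over the list alone. HMGN2 stood at -1.30 and HMGB2 at -1.11, neither passing over all genes. This list holds the gene the study itself names, so it is not independent evidence of a direction.

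Genes of cell adhesion, matrix and growth factor response were higher with the mimic as groups. All 20 measured extracellular matrix genes had a positive mean change, with a median of 0.75. None passed over all genes and 11 rose when adjusted over the list alone. COL4A1, a basement membrane collagen, stood at 2.21 in Li-7 and 0.73 in HEP-G2, and VTN, vitronectin, at 0.68 and 2.29. Under the 95th percentile of the negative control probe sets lay COL4A1 on both HEP-G2 arrays and the Li-7 control array, and VTN on the Li-7 control array. Among 24 integrin and focal adhesion genes the median was 0.49, with 0 passing over all genes and 7 rising when adjusted over the list alone, and ITGAV, the integrin alpha V chain, stood at 1.66 (adjusted p = 0.0589). The TGF-beta response list (18 genes) had a median of 0.59, with 0 passing over all genes and 3 rising when adjusted over the list alone. CCN1, a matricellular protein, was at 1.17 in Li-7 and, from a control value under that percentile, at 2.95 in HEP-G2. Camera called the matrix list (adjusted p = 3.55e-07), the integrin list (adjusted p = 2.54e-05) and the TGF-beta list (adjusted p = 0.000716) up. It did not do so with an estimated correlation (adjusted p = 0.740 for each), which called no list.

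Among 21 p53 targets the median was 0.36. TP53INP1 rose over all genes and 3 members rose when adjusted over the list alone, while CDKN1A, the p21 cell cycle inhibitor, stood at 1.01 in Li-7 and 2.16 in HEP-G2 (adjusted p = 0.0880). Not all members were higher. Chosen after their values were seen, MDM2, the main negative regulator of p53, stood at -1.62 in Li-7 and 0.87 in HEP-G2, RRM2B at -0.81 and 0.90, and ZMAT3 at -0.79 and -0.40. The apoptosis regulators had a median of 0.25, with 2 of 15 rising when adjusted over the list alone and 0 over all genes. The members with the largest changes, BIRC2 (1.32), MCL1 (0.96) and CFLAR (0.75), are known to restrain cell death. The RAS/MAPK response list had a median of 0.42 and the NF-kB and inflammatory list one of 0.71, and in each 0 members passed over all genes and 2 rose when adjusted over the list alone. The epithelial-mesenchymal transition list had a median of 0.23 and no member passing either way, and its members moved unevenly. KRT19, an epithelial keratin, stood at -0.23 in Li-7 and 2.59 in HEP-G2, CLDN4, also epithelial, at 0.55 and 1.23, and CDH2 at 0.98 and 0.87. VIM stood at 0.29 and 1.33, with both HEP-G2 values (4.16 and 5.49) under the 95th percentile of the negative control probe sets. In Li-7 the medians of the p53, RAS/MAPK and transition lists (0.27, 0.20 and 0.24) lay within the central 95% of matched random lists, while those in HEP-G2 (0.59, 0.69 and 0.45) lay above it. For the apoptosis and NF-kB lists the Li-7 medians (0.34 and 0.76) lay above it and the HEP-G2 medians (0.21 and 0.36) within it. Adjusted p values of camera were 0.00917 for p53 targets, 0.0473 for apoptosis, 0.0200 for RAS/MAPK, 0.0436 for NF-kB and 0.0200 for the transition list. With an estimated correlation, which called no list, camera made none of these calls (adjusted p = 0.740 for each).

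Cholesterol biosynthesis genes were called up (camera's adjusted p = 0.00243), but not with an estimated correlation (adjusted p = 0.740), which called no list. The median was 0.46, although the lines differed in value. It was -0.10 in Li-7 and 1.01 in HEP-G2, where 9 of 18 members were at least 2-fold higher. HMGCS1, an early enzyme of the pathway, stood at 0.38 in Li-7 and 1.48 in HEP-G2. Genes of fatty acid synthesis and use had a median of 0.33, at 0.11 in Li-7 and 0.61 in HEP-G2, and PLIN2, a lipid droplet protein, stood at 1.18 and 1.20. No member of either list passed over all genes, and 0 of 18 and 1 of 19 rose when adjusted over the list alone. The fatty acid list was called up by camera too (adjusted p = 0.0473), and again not with an estimated correlation (adjusted p = 0.740).

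The remaining 12 of the 27 lists were not called. Interferon-stimulated genes, which foreign RNA can induce, had a median of 0.015 (adjusted p = 0.796), with 0 of 20 passing over all genes and 2 rising when adjusted over the list alone. IRF9 stood at 1.79 and IFIT1 at -0.96, but IFIT1 lay under the 95th percentile of the negative control probe sets on all 4 arrays and IRF9 on the Li-7 control array. The unfolded protein and integrated stress response list had a median of -0.31 (adjusted p = 0.0677), with ASNS falling over all genes and, adjusted over the list alone, 4 falling and 1 rising. ATF4, its central transcription factor, stood at -1.19 and DDIT3 at 1.17, the latter from control values under that percentile in both lines. In the small RNA pathway list (median 0.14, adjusted p = 0.119), no gene passed over all genes and 4 rose and 1 fell when adjusted over the list alone. DROSHA, which processes primary microRNA transcripts, stood at -1.37 and DICER1 at 1.11. Medians were 0.37 for hepatocyte function (adjusted p = 0.0616), 0.24 for fetal liver markers, -0.067 for Wnt targets, 0.049 for PI3K, AKT and mTOR signalling, 0.021 for hypoxia and glycolysis, -0.12 for ribosomal proteins and -0.015 for the NRF2 list. Oxidative phosphorylation had a median of 0.065, a mean of -0.10 and a test pointing down (adjusted p = 0.470). Markers of blood, endothelial and stromal cells had a median of 0.14 (adjusted p = 0.956). In these last 9 lists, 0 members passed over all genes and 0 when adjusted over the list alone. The ribosomal list measured 13 genes and the oxidative phosphorylation list 19, and RPS28 and ATP5F1D, which fell, are members of neither. Of 51 ribosomal protein genes gathered by symbol after the results were seen, 2 fell over all genes (RPS28 and RPS15A) and 34 were lower in both lines, with a median of -0.073 in Li-7 and of -0.32 in HEP-G2, the latter under all matched random lists.

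**Figure D3:**
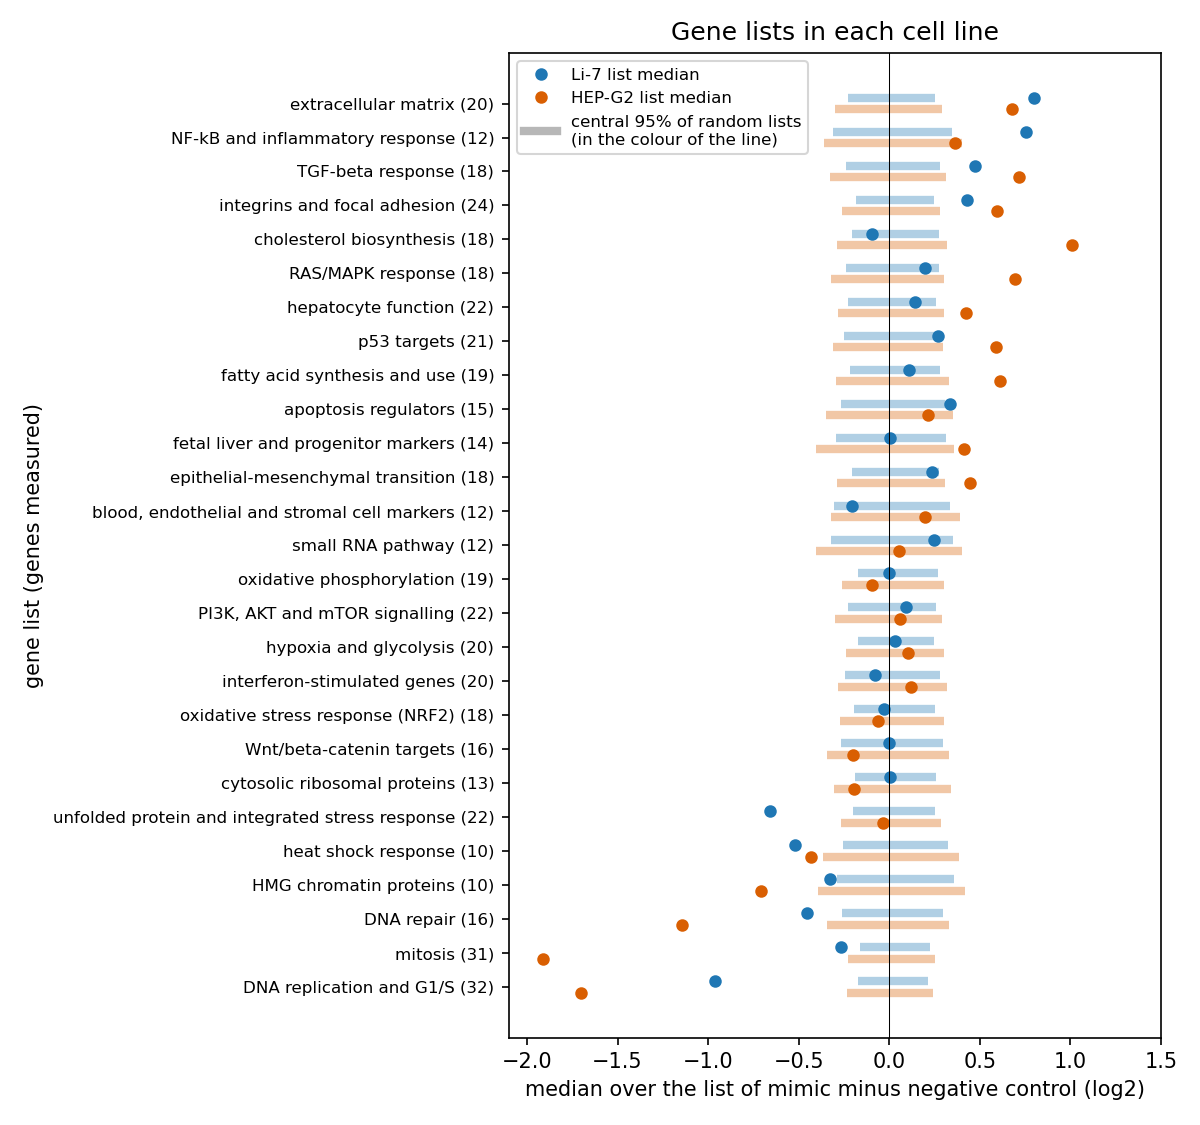
Median over each of 27 gene lists of the difference between mimic and negative control (log2, x axis), 1 point per line and list, with the number of genes measured after each list name (y axis). Bars span the central 95% of medians of 10000 random lists matched on expression, and mitosis stands at -0.27 in Li-7 and -1.91 in HEP-G2.

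In Li-7 taken alone, 461 genes were at least 2-fold higher and 510 at least 2-fold lower with the mimic, as differences between single arrays with no test. The lowest differences after HMGA1 were those of TTYH3 (-3.90), GPX2, a glutathione peroxidase (-3.87), SLC25A1 (-3.77), H2BC14 (-3.50), GNPDA1 (-3.27), CLN6 (-3.15), HSPB1 (-3.08), REG4 (-2.95) and CNN2, a calponin (-2.87). The highest were those of FILIP1L (3.01), NT5E (2.65), TNC, the matrix protein tenascin C (2.65), PLAU, urokinase (2.46), TP53INP1 (2.36), KLHL4 (2.34), SLC16A4 (2.33), ARRDC3 (2.32), NGEF (2.29) and the transcription factor ETS1 (2.27). REG4 lay under the 95th percentile of the negative control probe sets on both arrays, and FILIP1L, TNC, TP53INP1, KLHL4, SLC16A4 and NGEF did so on the control array. List medians outside the central 95% of random lists included extracellular matrix (0.80), NF-kB (0.76) and the unfolded protein and integrated stress response (-0.66). Of the 612 negative control probe sets, 27.5% differed at least 2-fold between the Li-7 arrays, against 7.84% of the genes used. Those at or above the genes' expression filter (median value 5.96) did so in 38.3%. Among the 3096 dimmest genes used (median value 5.69) the share was 7.53%. The negative control probe sets thus changed more often than genes of like brightness, so their share is no like-for-like background for the gene counts.

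In HEP-G2 alone, 714 genes were at least 2-fold higher and 777 at least 2-fold lower, again without a test. The highest differences were those of TMC7 (4.32), the early response factor EGR1 (3.96), ANKRD1 (3.58), BCL2A1, a relative of BCL2 (3.36), PROZ, protein Z (3.21), the chemokine CCL20 (3.10), RAB3B (3.00), CCN1 (2.95), JUN (2.80) and FABP1, the liver fatty acid binding protein (2.80). The lowest were those of RPS28 (-4.57), MYORG (-3.39), TSN, translin (-3.27), HMGA1 (-3.17), HSPB1 (-3.05), H2BC14 (-2.99), SLC25A1 (-2.95), TBL1X (-2.89), KIF20A, a mitotic kinesin (-2.85), and SLC29A4 (-2.80). SLC29A4 and JUN lay under the 95th percentile of the negative control probe sets on both arrays, and TMC7, EGR1, BCL2A1, PROZ and CCN1 did so on the control array. TMC7 and JUN were higher in Li-7 too (2.02 and 1.55) but did not pass the common test (adjusted p = 0.0601 for each). Of the negative control probe sets, 34.6% differed at least 2-fold between the HEP-G2 arrays, against 12.04% of the genes used. The share was 44.8% for those at or above the genes' expression filter and 7.95% for the 3096 dimmest genes used. Here too the negative control probe sets are no like-for-like background for the gene counts.

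The lines moved together more than apart. Across genes, which are not independent replicates, Pearson's r between the changes was 0.469 and Spearman's rho 0.439. Over the negative control probe sets r was 0.0629, and over those at or above the genes' expression filter it was 0.149. The correlation was 0.634 in the brightest of 4 equal groups of genes and 0.216 in the dimmest. At least 2-fold lower in both lines were 218 genes, where independent lists would share 32.0, and 128 were at least 2-fold higher in both, where 26.6 would be shared. Among the 201 negative control probe sets at or above that filter, 21 were lower and 9 higher in both, against 13.4 and 4.91. Only 18 genes moved at least 2-fold in opposite directions, against 58.3 for independent lists. Of the 2098 genes at or beyond 2-fold in either line, 81.6% had the same sign in both. The lines share no array, so no part of this comes from a shared control array. Both were compared with a negative control oligonucleotide, however. An effect of that oligonucleotide in both lines would also appear as a shared change, and none was measured.

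The widest gaps between the lines were where one line moved and the other hardly did or went the opposite way. EGR1 stood at -1.11 in Li-7 and 3.96 in HEP-G2, GPX2 at -3.87 and 0.24, ANKRD1 at -0.35 and 3.58, JMJD8 at -2.42 and 1.01, and PROZ at -0.15 and 3.21. In the other direction, DKK4, a secreted Wnt inhibitor, stood at 1.91 in Li-7 and -1.35 in HEP-G2, NGEF at 2.29 and -0.59, MYORG at -0.54 and -3.39, TNC at 2.65 and -0.18 and KIF20A at -0.09 and -2.85. EGR1, PROZ, DKK4 and MYORG lay under the 95th percentile of the negative control probe sets on both Li-7 arrays, and JMJD8, NGEF and TNC on both HEP-G2 arrays, so for these genes the change in that line rests on values near background. None of these differences could be tested with 1 array per group.

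The lines themselves differed far more than either did with the mimic. HEP-G2 held the transcripts of secreted liver proteins that were at background in Li-7. Each gene named here lay under the 95th percentile of the negative control probe sets on both arrays of the dimmer line, so its difference is given as a lower bound against that level. On the log2 scale, HEP-G2 was higher by at least 9.44 for AHSG, fetuin A, 9.20 for APOA2 and 8.57 for APOB, both apolipoproteins, 7.82 and 7.79 for the fibrinogen chains FGG and FGA, 7.60 for TF, transferrin, and 6.74 for A2M. AFP (at least 8.58) and GPC3 (at least 7.71), markers of fetal liver and of hepatocellular carcinoma, and VSNL1 (at least 8.03) were also higher in HEP-G2. Li-7 was higher by at least 8.21 for TMSB4X, 7.98 for ANXA1, 7.84 for UCHL1, a neuronal deubiquitinating enzyme, 7.81 for LDHB, a lactate dehydrogenase subunit, 7.24 for CD9, 7.002 for VIM, vimentin, 6.97 for the protease MMP7, 6.58 for VSIG1, 5.52 for TM4SF18 and 5.10 for CLMP. Each of these passed on its measured values, with adjusted p values of limma between 1.31e-06 and 4.33e-06.

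Between the lines, 5563 of 12381 genes passed, 3003 higher and 2560 lower in Li-7. That excess of higher genes turned with median centring, which gave 2684 higher and 2967 lower. The spread behind these calls is the disagreement between the treatments about the line difference, as no replicate cultures were measured. Culture medium differed with the line, so no difference can be assigned to the line alone. All 22 measured hepatocyte function genes had lower values in Li-7 (median -6.48), and 20 were lower both over all genes and adjusted over the list alone. Also called lower in Li-7 were cholesterol biosynthesis (14 of 18 lower over all genes, 16 adjusted over the list alone) and Wnt targets (11 of 16, 11 adjusted over the list alone). So were the unfolded protein list (14 of 22, 14 adjusted over the list alone), p53 targets (12 of 21, 12 adjusted over the list alone) and fatty acid genes (12 of 19, 12 adjusted over the list alone). Mitosis (27 of 31 higher, 29 adjusted over the list alone), replication (18 of 32, 20 adjusted over the list alone), integrins (16 of 24, 16 adjusted over the list alone) and the epithelial-mesenchymal transition list (14 of 18, 14 adjusted over the list alone) were called higher. Camera's adjusted p values at the preset correlation ran from 1.05e-15 for hepatocyte function to 0.00767 for replication. They may be far too small where list genes move together. With an estimated correlation none of the 10 calls was made (adjusted p = 0.959 for each). That run cannot decide, since it called no list here and missed every shifted list in the simulation of the mimic response. The other 17 lists were not called, and in 3 of them the signs were mixed. Extracellular matrix had a median of -0.049 and a mean of 0.26 with a test pointing down, the NRF2 list a median of -0.16 and a mean of 0.41 with a test pointing down, and the small RNA pathway a median of -0.057 and a mean of 0.17 with a test pointing up. The count of genes past the threshold was 1 with an ordinary t statistic.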

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

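The tests of explanations in this part were chosen only after the result was seen, and the differences between lines below were not tested, since each rests on 1 array per group.

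Among the named genes, 5 moved at least 1.5-fold in opposite directions in the lines. The difference of the changes, Li-7 minus HEP-G2, was -5.07 for EGR1, -3.43 for JMJD8, 3.26 for DKK4, 2.87 for NGEF and -1.60 for AHSG. In each of these 5 a line lay under the 95th percentile of the negative control probe sets on both arrays, Li-7 for EGR1, DKK4 and AHSG and HEP-G2 for JMJD8 and NGEF, so the opposite directions rest on values near background. The p53 targets MDM2 (-2.50) and RRM2B (-1.71), chosen after their values were seen, went lower in Li-7 and higher in HEP-G2 with all values above that percentile.

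The mitosis list differed between the lines by a median of 1.60 (Li-7 minus HEP-G2 change), outside the range of -0.16 to 0.23 of matched random lists. A ceiling of the signal in Li-7, where these genes are brighter, is not borne out. In that line the 26 replication genes within the same range of control values had a median change of -1.03, against a random range of -0.19 to 0.23. A brightness-dependent trend between arrays is not either, as the median difference stayed at 1.49 after cyclic loess. A response that differs between the cell lines may remain, but chance variation between single cultures cannot be told apart from it without replicate arrays.

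Among the 3739 probe sets without a gene name used here, which the comparisons leave out, 767 lay above the 95th percentile of the negative control probe sets on all 4 arrays. Of these, 20 were at least 2-fold lower and 4 at least 2-fold higher with the mimic in both lines, shares of 2.61% and 0.522%, against 2.16% and 0.900% of 5555 named probe sets above that level and 0 of 10 negative control probe sets, too few for a comparison. Over all 3739, the shares were 0.909% lower and 0.294% higher, and the negative control probe sets reached 4.74% and 3.10% and the named ones 1.25% and 0.745%, so the shares over all probe sets decide nothing. A pair of bright ones was chosen after their values were seen. TC1100008612.hg.1 went from 16.24 to 13.83 in Li-7 and from 16.34 to 12.26 in HEP-G2, and TC0X00010648.hg.1 from 13.81 to 11.83 and from 13.72 to 11.78. What they measure is not known here.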

How the results depend on the processing

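One alternative, the filter on negative control probe sets, was chosen after seeing the data. The number of genes past the threshold in the common mimic response, 52, was 465 after quantile normalization, 23 after cyclic loess, 366 with the filter at the median gene, 200 with the filter on negative control probe sets, 411 with an intensity trend, 1 with an ordinary t statistic and 0 without the block of cell line (182 genes there at an unadjusted p under 0.05). It was 59 with median centring and with no filter, 50 with the mean of probe sets and 49 with robust eBayes. All 52 genes remained past the threshold with quantile normalization, median centring, no filter and the trend, 23 did after cyclic loess, and the direction was the same for each tested gene in all settings. Falls made up 80.8% of calls, but 58.7% with quantile normalization, 61.6% with the trend, 65.3% with the filter at the median gene and 70.5% with the filter on negative controls. Among the 52 genes with the lowest p, the share was 78.8% with quantile normalization and with the trend. It was 84.6% there with the filter at the median gene. As deposited, 62.6% of the 465 genes with the lowest p fell. In these settings the lower shares thus went largely with the larger number of calls. The filter on negative controls was not examined in this way, and why the number of calls shifted was not tested. HMGA1 stayed at -3.59 with an ordinary t statistic and without the block, where it no longer passed, and its mean change ran from -3.59 to -3.50 over 11 alternatives, passing in 9 (adjusted p from 0.000712 to 1). The cell line difference gave 1 gene with an ordinary t statistic, GLRX3, also the 1 gene of the mimic response there, whose residual is close to 0 and which was chosen after its values were seen. Median centring moved the median line difference of all genes from 0.025 to -0.10 (it was also negative with quantile normalization, -0.035, and with no filter, -0.047) and turned its split from 3003 higher and 2560 lower in Li-7 to 2684 higher and 2967 lower. A 1.5-fold limit gave 3112 genes in Li-7 and 4032 in HEP-G2. With an estimated correlation camera called 0 lists for the mimic response and 0 for the cell line difference (0 and 0 at an unadjusted p under 0.05). It also called 0 of 20 shifted lists in the simulation, so its lack of calls says nothing about any one list. No called value of a named gene, list or count changed sign, apart from the split of the line difference and the single calls with an ordinary t statistic. Those were a rise with the mimic and a lower value in Li-7, each against the majority of calls in the main fit. The other values were counted once per setting and per comparison or line, and a tested value called in neither run counted as the same. By that count 770 list medians were the same, 29 weaker, 2 stronger and 5 moved. The weaker ones include all 15 list calls of the mimic response and all 10 of the line difference, lost with the estimated correlation. Of the values of named genes in the common response, 1177 were the same, 84 stronger and 58 weaker. Leaving out a line leaves 1 array per group and no test, and the labels pair no replicates across groups, so cell line was the one block. The seed site search, with its alternatives, was not run. Genes near the negative controls are measured least well.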

Other observations

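The groups and tests in this part were chosen after the results were seen. Replication-dependent histone genes, whose transcripts are made in S phase, had medians of -0.60 in Li-7 and -0.79 in HEP-G2 over 52 genes, both under all 10000 matched random lists, with 45 of the 52 lower in both lines. H2BC14 was the 1 member that fell over all genes, while H1-5 stood at -1.57 and H2AC4 at -1.50 without passing. Many of these genes are near-identical, so their probe sets may not be independent, and the 51 histone genes other than H2BC14 reached a share of only 0.201 of its fall. The cell cycle regulator FOXM1 stood at -1.20 in Li-7 and -2.35 in HEP-G2, and MYBL2 at -1.07 and -1.66.

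TEAD4, a DNA-binding partner of the coactivator YAP, fell (-2.44, with 3 of its 4 values under the 95th percentile of the negative control probe sets), while the medians over 15 genes known as YAP and TEAD targets were 0.83 in Li-7 and 1.34 in HEP-G2. NT5E was the 1 member that rose over all genes, and 10 of the 15 were higher in both lines, among them CCN1, AXL (0.92 and 1.34) and CRIM1 (0.94 and 1.24). The other members were lower in one line, CCN2 (-0.40), ANKRD1 (-0.35), LATS2 (-0.14) and F3 (-0.092) in Li-7 and ARHGEF17 (-0.46) in HEP-G2. Early response genes, most of them transcription factors, had medians of 0.61 and 1.45 over 14 genes, 9 of them higher in both lines. By the mean of the lines, JUN (1.55 and 2.80), KLF10 (1.40 and 1.88) and KLF6 (1.16 and 1.83) led them. EGR1 had the largest rise in HEP-G2 (3.96) but stood at -1.11 in Li-7. None of the early response genes passed over all genes.

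Falls outnumbered rises among the genes past the threshold. A brightness-dependent trend between arrays would even this out once removed, yet 75% of the 52 genes with the lowest p fell after cyclic loess (exact binomial 95% interval 61.1 to 86.0). Unequal value distributions as the whole cause would do so after quantile normalization, where 78.8% of the 52 fell (65.3 to 88.9). Over all 465 calls made there the share was 58.7% (54.1 to 63.2), against 62.6% of as many lowest-p genes as deposited, so a part of the excess from that source stays open. These intervals treat genes as independent trials, which they are not, and do not measure the variation between single arrays. Of 44 called genes outside replication, mitosis, repair and histone genes (with E2F8, BRIP1 and MND1 left out as well), 77.3% fell. The excess of falls was thus not confined to those genes. Whether lower proliferation was the whole cause cannot be decided from this, as genes outside those lists may follow it too. Direct repression by the mimic may contribute. Genes at least 2-fold lower in both lines were 6.81 times as many as independent lists would share, against 4.81 for genes higher in both, but without 3 prime UTR sequences this cannot be told apart from a common secondary response.

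Some genes fell far below their relatives. H2BC14, RPS28, ATP5F1D and HSPB1 had mean changes of -3.24, -3.50, -2.72 and -3.06. The medians of their relatives, gathered by symbol, were -0.65, -0.18, 0.045 and -0.0036. Those of HSPB1 were a broad set picked by heat shock symbols, which also took in HSPG2, a matrix proteoglycan (0.70). In that set HSPB8, also a small heat shock protein, stood at 1.59 without passing. The relatives' medians reached at most a share of 0.201 of the fall, which restates the pattern and is no test of a change of the whole family. Relatives about as bright or brighter reached a median share of 0.0844. They come from the same relatives, below which the members were picked, so this cannot test the brightness of the probe set. In the ribosomal family RPS15A also fell (-1.87). The members were picked for their large falls and the families built around them, so that each is the lowest of its family, in 4 of 4, was largely fixed by the choice and says nothing about direct repression by the mimic. Seed sites were not searched, and cross-hybridisation between gene copies was not tested.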
